A study of Bos taurus with 13 samples.

How the data were processed

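Gene expression was measured in bovine embryos produced in vitro, on 13 one-colour arrays in 4 groups. These were embryos cultured without feeder cells at 5% O2 (3 arrays), without feeder cells at 20% O2 (3 arrays), with BOEC at 20% O2 (3 arrays) and with VERO cells at 20% O2 (4 arrays). Per the labels' protocols, putative zygotes were cultured at 25 embryos to a well of 500 µl, RNA was isolated from batches of 10 embryos with a DNase step, and 25 ng was amplified and labelled with Cy3. The sample labels give blastocysts at 192 hours post insemination. The series' design text gives the 16-cell stage at 96 hours instead, and the extraction protocol also speaks of 16-cell embryos; the sample labels were followed. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

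Per the submitters' processing notes, the authors read the arrays with Agilent Feature Extraction 10.7.3.1. Per the file headers, the deposited processed intensities had their background removed by spatial detrending, were corrected for multiplicative trends across the array, had low values replaced by a surrogate, and were not normalized between arrays. The authors' deposited series matrix holds log2 values; set against the scanner values, each column equals log2 of the median spot signal minus the array's median, with no background subtraction, so its scale and centring are known. Its column medians lay between -0.0227 and 0.0.

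Each array held 61549 spots, of which none was saturated and 6 to 23 were marked as outliers and left out with the control spots. The 75th percentile of the processed signal ran from 217 to 586 per array, and 56.4% to 65.9% of probes were well above background. Both lowest values were those of BOEC replicate 4, 1 of the 3 BOEC arrays (the next lowest arrays had 322 and 58.4%). Genes reported as not well above background with BOEC thus rest in part on this dim array. Arrays give no counts, so their number limits the precision. The levels used here are log2 of the processed signal minus that array's 75th percentile. Spots of a probe were averaged, and 8365 probes present as a second copy were averaged with their twin (r between copies 0.989 to 0.994 per array). Of the 53034 resulting probes, 23335 were named through their accession and a RefSeq gene table of assembly ARS-UCD2.0 (used for names alone), 12632 through a symbol, 411 through a synonym and 1436 by the name on the array. A further 5952 carried small RNA names, 894 endogenous retrovirus clone names and 14 a luciferase name, and 8360 stayed unnamed. Positions are those of the array files, on UMD 3.1 (bosTau6).

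A probe was kept if it was well above background on every array of at least 1 group. Each gene was represented by the kept probe with the highest mean, which left 16300 features, of which 16278 had a value on every array. Differences between groups were tested with limma (lmFit and eBayes, residual degrees of freedom 9, prior degrees of freedom 2.66) on all 13 arrays, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. The 6 comparisons between groups and the F test over the 4 groups were fixed before the data were examined, as were the gene lists, the rule for naming genes and most of the alternatives. Where a gene had other kept probes, these mostly ran the same way. Of the called genes with another probe, all probes had the same sign for 54 of 58 (20% against 5% O2), 1947 of 2066 (BOEC against none), 3535 of 3745 (VERO against none), 5 of 5 (BOEC against VERO), 301 of 303 (BOEC against 5% O2) and 864 of 892 (VERO against 5% O2). Another probe went the opposite way at an unadjusted p below 0.05 for 0, 32, 30, 0, 0 and 1 of these genes.

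Genes named in the text follow a rule: in each of the first 4 comparisons, the 10 largest rises and the 10 largest falls among called genes with a symbol and non-overlapping groups, and 4 and 4 in the last 2. Beside each list, up to 4 called members with the largest change are given, or, where none was called, the 2 members with the smallest p as values. The array-level check genes were ACTB, GAPDH, H2AZ1, YWHAZ and SDHA. A gene that was well above background on no array of a group has only a bound there; where some arrays measured it, the fitted fold is given with their number and rests in part on signal near background. Its "at least" fold sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own.

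The 31 lists comprise 23 gene lists and 8 lists of markers of other cells that a batch of embryos could carry. They were tested with camera in limma at a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison. Lists with fewer than 5 tested members would not have been tested. They were trophectoderm, inner cell mass and pluripotency, primitive endoderm, interferon tau and conceptus products, interferon-stimulated genes, inflammation and NF-kB targets, HIF1 targets, glycolysis, oxidative phosphorylation, antioxidant defence and NRF2 targets, metal response, p53 targets, heat shock, unfolded protein and integrated stress response, cholesterol, fatty acid and lipid droplet metabolism, tight junctions and fluid transport, cell cycle, apoptosis, DNA methylation and imprinting, maternal transcripts, ribosomal proteins, and growth factor signalling. The cell lists were oviduct secretory, oviduct ciliated, kidney, stromal, leukocyte, cumulus, red blood and sperm markers. Median log2 fold changes of lists use fitted values; with dim members set to their bound, a list's median moved by at most 0.14 and changed sign in 0 of 186 tests. A list's median, mean and test differed in sign in 27 of 186 tests, all among lists that were not called.

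Correlations of fold changes were set beside 1000 simulated draws of unchanged groups sharing the same control arrays, and the overlap of calls beside 100 such draws. The separation of the groups was tested with 100000 permutations, one-sided. On simulated data with 50 genes changed at each of 4 sizes among 16278 genes, limma recovered 18%, 52%, 82% and 92% of 1.5-, 2-, 3- and 4-fold changes for 20% against 5% O2, calling 9 of 16053 unchanged genes. For VERO against no feeder it recovered 20%, 62%, 90% and 96%, calling 8 of 16053. Arrays lay on 2 slides, scanned separately, of 5 and 8 arrays, each holding all 4 groups, so each comparison was also fitted with the slide as a block and within each slide.

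Alternatives were quantile normalization, median centring over detected probes, normexp background correction (offset 50), no probe filter, a filter asking for all 13 arrays, the authors' series matrix, trended and robust variances, array weights, replicate or slide blocks, every probe, the mean of a gene's probes, a 2-fold minimum, the 2 groups alone, leaving out each array, and an estimated correlation for lists. Fits on each slide alone, the slide block for lists, named genes and correlations, and features with a symbol alone were added after seeing the data. The separation of the groups was not tested with the slide as a block. Named genes were run under 20 of these: each array left out, quantile normalization, median centring, normexp, both blocks, the series matrix and the mean of probes. The 18 alternatives whose range is given for lists were each array left out, quantile normalization, median centring, normexp and both blocks. Those ranges leave out the estimated correlation, which ended every call of a list and is given apart beside each. R 4.3.3, limma 3.58.1, the data.table package (1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.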

Results

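Transcript levels were measured in batches of bovine blastocysts, the embryo stage with an outer trophectoderm and an inner cell mass, sampled 192 hours post insemination. Putative zygotes made in vitro had been cultured in SOF medium under 4 conditions. The first was without feeder cells at 5% O2, which the labels call the control (3 arrays), and the second without feeder cells at 20% O2 (3 arrays). In the others, embryos were co-cultured at 20% O2 with BOEC (3 arrays) or with VERO cells (4 arrays). VERO is an established line of monkey kidney epithelium; BOEC is left unexplained in the labels and is in common use for bovine oviduct epithelial cells. The study's stated purpose was to compare the blastocyst transcriptome between these co-culture systems. Levels below are log2 signal relative to each array's 75th percentile, and changes are log2 fold changes unless a fold is given.

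The 4 groups differed as whole profiles. Arrays of different groups lay 81.8 apart on average over the 16278 features with a value on every array and arrays of the same group 62.8, a difference of 18.96 that 100000 permutations of the group labels reached with a one-sided permutation p of 2e-05. The first principal component carried 35.2% of the variance. On it the 20% O2 arrays without feeder stood at one end and the VERO arrays with BOEC replicate 3 at the other, with the 5% O2 arrays on the side of 20% O2 and the other BOEC arrays on the side of VERO. In limma's F test over the 4 groups 3410 features passed, and 3175 with the slide as a block. The count was 1925 and 1793 without 20% O2 replicates 1 and 3 and 2265 and 2126 without VERO replicates 1 and 4, was 201 in slide 2 alone, and was 0 in slide 1 alone by limma, where 3074 had an unadjusted p below 0.05. None of ACTB, GAPDH, H2AZ1, YWHAZ and SDHA was called in any comparison; between the oxygen levels ACTB changed by -0.01 (adjusted p = 0.979) and GAPDH by -0.93 (0.308).

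**Figure D1:**
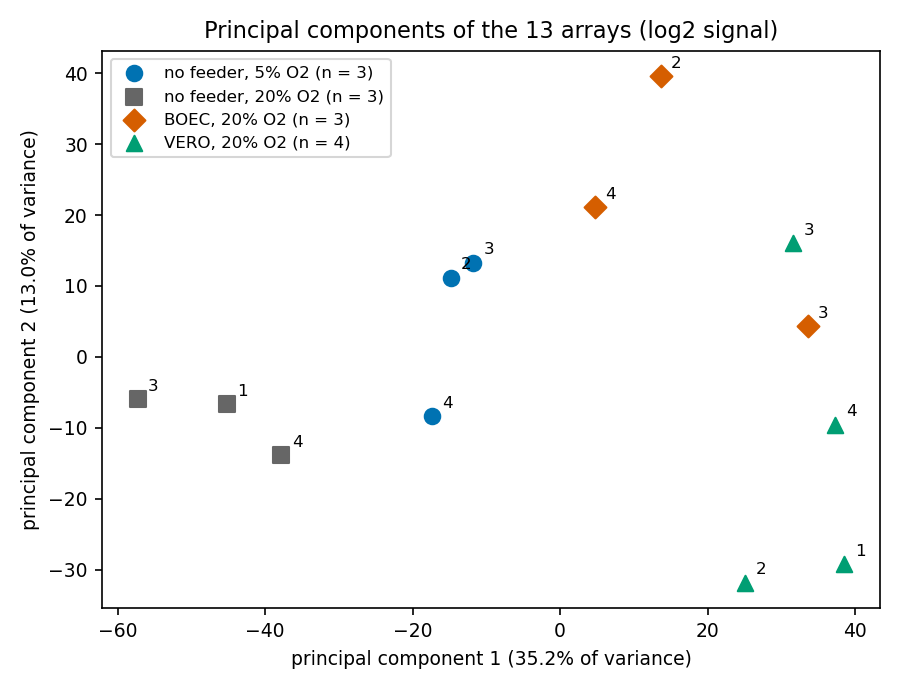
Each point is 1 array on the first 2 principal components (in units of log2 signal), coloured by group. The 3 arrays at 20% O2 without feeder lie between -57.3 and -37.8 on the first component and the 4 VERO arrays between 25.1 and 38.5.

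The first comparison asked what 20% O2 did in the absence of feeder cells, against 5% O2. PDZK1, a scaffold protein of transporters in apical membranes, was lower at 20% O2, at -1.72 ± 0.38 against 0.22 ± 0.30 (SD, n = 3 each), a 3.85-fold fall (adjusted p = 0.0133). ARHGDIB fell 4.33-fold (adjusted p = 0.0133) and SERPING1, the C1 inhibitor of complement, 5.30-fold (adjusted p = 0.0465). TFAP2A, a transcription factor of the trophectoderm, fell from -0.13 ± 0.26 to -1.35 ± 0.23. SLC39A4, a zinc importer, rose from 2.89 ± 0.05 to 3.87 ± 0.11 (adjusted p = 0.0287).

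Other falls at 20% O2 were those of TGM1, a transglutaminase (3.70-fold), CELF3, an RNA-binding protein (2.72-fold), and LYZ2, a lysozyme (2.37-fold). FCGR3A, FASLG and LIPC, an Fc receptor, the Fas ligand and hepatic lipase, were not well above background on any array at 20% O2 and were at least 2.29-, 1.74- and 2.14-fold lower (adjusted p = 0.0482, 0.0287 and 0.0426). Rises were those of TMEM164 (2.39-fold), the actin-binding ABLIM1 (2.38-fold), the vesicle protein SYNGR2 (2.24-fold), RASGRP2, an activator of Rap GTPases (2.18-fold), the mitotic kinesin KIF18B (2.12-fold), TANC1 (2.12-fold), PYGO1, a Wnt coactivator (1.97-fold), and the cadherin CELSR2 (1.96-fold). GAL3ST4, a galactose sulfotransferase not well above background on any array at 5% O2, was at least 2.60-fold higher (adjusted p = 0.0382). PDZK1 (array transcript ENSBTAT00000007638) lies at 21755127 to 21801218 on chromosome 3, ARHGDIB (ENSBTAT00000007933) at 95376923 to 95395815 on chromosome 5 and TFAP2A (ENSBTAT00000001651) at 45480546 to 45499034 on chromosome 23.

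In all, 70 of 16300 features passed in limma, 43 up and 27 down, and 3264 had an unadjusted p below 0.05; the series matrix, whose median over all genes lay at -0.12, gave 7 up and 30 down. With the slide as a block 31 passed (21 up, 10 down), among them 8 of the 20 named genes, and SERPING1 did not (adjusted p = 0.0609); each slide alone gave 0 in limma (1837 and 2059 at an unadjusted p below 0.05). The count rested on single arrays: it was 2, 0 and 8 without 5% O2 replicates 2, 3 and 4, 6, 0 and 121 without 20% O2 replicates 1, 3 and 4, and 7, 129 and 31 without VERO replicates 1, 2 and 4. In limma's fits that called 0 without an array, 2560 and 2039 features had an unadjusted p below 0.05. With the replicate number as a block limma called 0 as well, none of the 20 named genes among them (2620 at an unadjusted p below 0.05). PDZK1 and ARHGDIB lost their calls without 5% O2 replicate 3 (adjusted p = 0.123 for both) or 20% O2 replicate 3 (0.0617 and 0.0581), and the other 18 named genes lost theirs without 5% O2 replicate 2 (0.0988 to 0.147), 5% O2 replicate 3 (0.136 to 0.156) or 20% O2 replicate 3 (0.127 to 0.189), many of them also without others. Normexp ended the calls of GAL3ST4, ABLIM1, PYGO1, CELSR2, FCGR3A, FASLG and LIPC (0.0843 to 0.762), and the series matrix those of the same 7 and of TMEM164, RASGRP2, KIF18B, TANC1, SLC39A4 and TFAP2A (0.0550 to 0.158). The mean of probes ended those of SYNGR2, RASGRP2, PYGO1, FCGR3A, TGM1 and CELF3 (0.0636 to 0.103) and quantile normalization that of FCGR3A (0.0537). Over the 20 alternatives run for named genes the adjusted p of the 20 genes ran from 0.00212 to 0.762.

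Of the lists, 6 were called between 20% and 5% O2, and all 6 calls were lost with an estimated correlation. Genes for interferon tau and other conceptus products, the secreted factors and steroid enzymes of the trophectoderm, fell (median -0.62 over 11 genes, camera adjusted p = 2.64e-04, adjusted p = 0.506 with an estimated correlation). None of the 11 was called alone by limma, and 6 were lower adjusted over the list alone; HSD3B1, a steroid dehydrogenase, differed by -1.42 (adjusted p = 0.0695) and PTGS2, a prostaglandin synthase, by -0.80 (0.0737). HIF1 targets, genes that hypoxia induces, fell (median -0.25 over 34, camera adjusted p = 7.53e-04, adjusted p = 0.506 with an estimated correlation), with 0 called and 1 higher and 5 lower adjusted over the list alone. The glucose transporter SLC2A3 differed by -0.62 (0.0538) and the vasodilator peptide ADM by 0.89 (0.0833). Glycolysis genes fell (median -0.28 over 23, camera adjusted p = 0.00227, adjusted p = 0.506 with an estimated correlation), with 0 called and 4 lower adjusted over the list alone; the phosphofructokinase PFKL differed by -0.66. Cholesterol genes fell (median -0.40 over 25, camera adjusted p = 7.53e-04, adjusted p = 0.568 with an estimated correlation), with 0 called and 2 lower adjusted over the list alone, HSD17B7 differing by -0.97 and INSIG1, a regulator of sterol synthesis, by -0.90. Unfolded protein and integrated stress response genes fell (median -0.14 over 31, camera adjusted p = 0.0299, adjusted p = 0.572 with an estimated correlation), with 0 called and 4 lower adjusted over the list alone, EDEM1 and CRELD2 differing by -0.72 and -0.70. The p53 targets rose (median 0.23 over 23, camera adjusted p = 0.0299, adjusted p = 0.506 with an estimated correlation), with 0 called, and 7 higher and 1 lower adjusted over the list alone, TP53INP1 differing by 0.61 and GADD45G by -0.82.

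These lists, with the slide as a block, kept their calls (adjusted p 4.995e-04 for conceptus products, 0.00102 for HIF1 targets, 0.00354 for glycolysis, 0.00102 for cholesterol, 0.0437 for the unfolded protein response and 0.0210 for p53 targets). Within slides 1 and 2 the medians were -0.68 and -0.62, -0.18 and -0.35, -0.06 and -0.37, -0.17 and -0.49, -0.08 and -0.24, and 0.03 and 0.26. HIF1 targets lost the call without 5% O2 replicate 3 (adjusted p = 0.0806) and glycolysis without the same array (0.120). The p53 targets lost it without 5% O2 replicate 4 (0.111) or 20% O2 replicate 3 (0.103). The unfolded protein response lost it without 5% O2 replicate 3 (0.0806), 20% O2 replicate 4 (0.110) or VERO replicate 4 (0.0695). Without single arrays some medians moved by over 1.5 times: to -0.14 and -0.18 for HIF1 targets and glycolysis without 5% O2 replicate 3, to 0.14 and -0.23 for p53 targets and the unfolded protein response without 5% O2 replicate 4, and to -0.21 for cholesterol without 20% O2 replicate 3. The p53 targets also lost their call under normexp (0.0568) and the unfolded protein response under quantile normalization (0.0673). With the replicate number as a block the unfolded protein response lost it too (camera adjusted p = 0.292, median -0.04). Over 18 alternatives the adjusted p ran from 9.53e-05 to 0.00251 for conceptus products, 6.15e-05 to 0.0806 for HIF1 targets, 6.65e-05 to 0.120 for glycolysis, 6.51e-06 to 0.0160 for cholesterol, 0.00563 to 0.292 for the unfolded protein response and 0.00797 to 0.111 for p53 targets.

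The second comparison asked what BOEC did at 20% O2. GPA33, a cell surface antigen of epithelia, rose 9.38-fold, from -3.99 ± 0.21 to -0.76 ± 0.34 (SD, n = 3 each, adjusted p = 6.79e-04). PDZK1 rose 6.79-fold, from -1.72 ± 0.38 to 1.04 ± 0.31, and ARHGDIB 6.65-fold, to 0.73 ± 0.07 (adjusted p = 5.31e-04 for both), and SERPING1 rose 6.43-fold. APBA2, an adaptor of the amyloid precursor protein, fell 7.81-fold (adjusted p = 0.00717, above background on 2 of 3 BOEC arrays).

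Further rises with BOEC were those of ALAS2, an enzyme of haem synthesis (8.68-fold), the fucosyltransferase FUT6 (8.59-fold), the actin-bundling LCP1 (7.82-fold) and the adhesion receptor ADGRF5 (6.99-fold). ADTRP and LIPC, which were not well above background on any 20% O2 array, were at least 2.88- and 4.01-fold higher (adjusted p = 0.00101 and 0.00145). Genes that fell and were not well above background on any BOEC array were lipoprotein lipase LPL (at least 5.91-fold, adjusted p = 0.0215), the proteasome subunit PSMA8 (at least 5.44-fold, 0.00157), the mitochondrial carrier SLC25A31 (at least 4.48-fold, 0.0172) and the allantoicase gene ALLC (at least 3.90-fold, 0.00108). Below background with BOEC were also SDR16C5, an enzyme of retinol metabolism (at least 2.77-fold, 0.00813), the defensin DEFB10 (at least 2.32-fold, 0.0187), the antibacterial BPI (at least 2.18-fold, 0.00276) and GAL3ST4 (at least 1.87-fold, 6.79e-04). PIWIL2, which acts in transposon silencing, fell 6.93-fold (above background on 2 of 3 BOEC arrays). GPA33 (ENSBTAT00000012054) lies at 1726504 to 1779667 on chromosome 3.

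In limma 2473 of 16300 features passed, 1136 up and 1337 down, and with the slide as a block 2351 passed (1062 up, 1289 down), including all 20 named genes; GPA33 changed by 3.78 on slide 1 and 2.96 on slide 2. Slide 2 alone gave 550 (177 up, 373 down) and slide 1 alone 0 in limma, where 2735 had an unadjusted p below 0.05. The count was 1309 and 1146 without 20% O2 replicates 1 and 3, and 1054 without BOEC replicate 3. Of the named genes 15 kept their calls without any array. ADGRF5 lost its call without 20% O2 replicate 3 (adjusted p = 0.0591) or BOEC replicate 3 (0.0507), DEFB10 without 20% O2 replicates 3 or 4 or BOEC replicate 3 (0.0536, 0.059 and 0.067), and LPL without 20% O2 replicates 3 or 4 or BOEC replicates 2 or 3 (0.0781, 0.0608, 0.0534 and 0.0731). PIWIL2 lost it without 20% O2 replicates 1 or 3 or BOEC replicate 3 (0.0557, 0.0508 and 0.0724), and SLC25A31 without 20% O2 replicate 1 or BOEC replicate 3 (0.054 and 0.0521). Under normexp 7 named genes lost their calls, LPL (0.132), BPI (0.466), DEFB10 (0.404), ALLC (0.173), GAL3ST4 (0.649), SDR16C5 (0.287) and SLC25A31 (0.165), and under the series matrix DEFB10 did (0.0916). Over the 20 alternatives run for named genes the adjusted p of the 20 genes ran from 2.37e-05 to 0.649.

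Conceptus product genes rose with BOEC (median 0.88 over 11, camera adjusted p = 0.00373, adjusted p = 0.528 with an estimated correlation), with 4 up and 0 down, and 8 up adjusted over the list alone. HSD3B1 rose by 2.25 (adjusted p = 0.0028), the aromatase CYP19A1 by 1.08 and the prostaglandin synthase PTGES by 0.77. Trophectoderm genes rose (median 0.22 over 20, camera adjusted p = 0.0349, adjusted p = 0.528 with an estimated correlation), with 4 up and 0 down, the same number adjusted over the list alone: TFAP2A by 1.55, ELF3 by 0.73, PTGS2 by 0.71 and SFN by 0.66. Ribosomal protein genes rose (median 0.10 over 47, camera adjusted p = 0.0349, adjusted p = 0.696 with an estimated correlation), with 2 up and 0 down (2 up adjusted over the list alone), RPL35 by 0.81 and RPL7 by 0.59. Maternal transcripts, stored in the oocyte, fell (median -0.63 over 18, camera adjusted p = 0.0214, adjusted p = 0.528 with an estimated correlation), with 1 up and 4 down (2 up and 7 down adjusted over the list alone). OOEP fell by 1.57, PABPC1L fell by 0.84, and KPNA7 was at least 2.49-fold lower, while the zona protein ZP3 rose by 0.78. Markers of ciliated oviduct cells fell (median -0.76 over 14, camera adjusted p = 0.0214, adjusted p = 0.528 with an estimated correlation), with 0 up and 6 down, also adjusted over the list alone. TPPP3 fell by 1.95, SPMIP6 fell by 1.58, TEKT2 fell by 1.07 and TUBA1A fell by 0.90.

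The adjusted p with the slide as a block was 0.00609 for conceptus products, 0.0343 for trophectoderm, 0.0329 for ribosomal proteins, 0.0179 for maternal transcripts and 0.0329 for ciliated markers. Within slides 1 and 2 the medians were 1.30 and 0.62, 0.20 and 0.30, -0.01 and 0.17, -0.27 and -0.79, and -0.54 and -0.63. Trophectoderm lost the call without 20% O2 replicates 3 or 4 or BOEC replicate 2 (adjusted p = 0.0566, 0.0725 and 0.112), ribosomal proteins without 20% O2 replicate 4 or BOEC replicate 4 (0.186 and 0.126) and ciliated markers without BOEC replicate 2 (0.0713). The trophectoderm median was 0.12 without 20% O2 replicate 3, and that of ribosomal proteins 0.06 without 20% O2 replicate 4 and 0.05 without BOEC replicate 4. Under normexp trophectoderm, maternal and ciliated genes (0.0689 each) and ribosomal proteins (0.504) lost it, the last 3 with medians of only -0.21, -0.04 and 0.05. Quantile normalization ended the calls of trophectoderm (0.0591) and ribosomal proteins (0.719, median 0.01). The replicate number as a block ended that of ciliated markers (0.0613, median -0.61). Over 18 alternatives the adjusted p ran from 3.89e-04 to 0.0419 for conceptus products, 0.0102 to 0.112 for trophectoderm, 0.00995 to 0.719 for ribosomal proteins, 0.00995 to 0.0689 for maternal transcripts and 0.0102 to 0.0713 for ciliated markers.

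The third comparison asked what VERO cells did at 20% O2. UPP1, a uridine phosphorylase, rose 16.6-fold, from -1.94 (SD 1.5, n = 3) to 2.12 ± 1.13 (SD, n = 4, adjusted p = 0.00216). PDZK1 rose 11.4-fold, to 1.80 ± 0.17 (adjusted p = 1.87e-05), and GPA33 12.3-fold, to -0.37 ± 0.54. FUT6 rose 15.4-fold, LCP1 13.6-fold, the nuclease DNASE1L3 12.4-fold and SERPING1 8.85-fold. TXNIP, an inhibitor of thioredoxin and of glucose uptake, was not well above background on any VERO array and was at least 4.29-fold lower (adjusted p = 4.53e-04).

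LIPC and RBMS3, an RNA-binding protein, neither well above background on any 20% O2 array, were at least 6.03- and 2.57-fold higher (adjusted p = 2.35e-04 and 0.00352). The chemokine CCL22 rose 8.93-fold (above background on 1 of 3 arrays at 20% O2). Not well above background on any VERO array were CHCHD6, a mitochondrial membrane protein (at least 4.78-fold lower, adjusted p = 0.00413), the cytochrome P450 gene CYP2C89 (at least 4.24-fold, 0.00155) and the serotonin receptor HTR5A (at least 3.44-fold, 0.00427). The same held for TMEM130 (at least 2.70-fold, 0.00278, measured on 2 of 3 arrays at 20% O2), GAL3ST4 (at least 2.19-fold, 1.31e-04), BHMT, a methyltransferase of homocysteine (at least 2.11-fold, 0.00192), and the arrestin-domain gene ARRDC4 (at least 1.72-fold, 3.13e-04). APBA2 fell 9.47-fold and HGFAC, a protease that activates hepatocyte growth factor, 8.77-fold (each above background on 2 of 4 VERO arrays). UPP1 (ENSBTAT00000011088) lies at 7528100 to 7556112 on chromosome 4 and TXNIP (ENSBTAT00000026724) at 21489097 to 21493251 on chromosome 3.

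In limma 4444 of 16300 features passed, 2337 up and 2107 down (3219 up and 1103 down with the series matrix, whose median over all genes lay at 0.18), and 4321 with the slide as a block. Slide 2 alone gave 1245, with most of them falls (441 up, 804 down), and slide 1 alone 0 in limma, where 3988 had an unadjusted p below 0.05. All 20 named genes kept their calls with the slide as a block and without any array, UPP1 changing by 2.16 and 5.43 within slides 1 and 2. Normexp ended the calls of RBMS3 (adjusted p = 0.218) and GAL3ST4 (0.0696), and over the 20 alternatives run for named genes the adjusted p of the 20 genes ran from 3.07e-07 to 0.218. The count was 2832 and 2416 without 20% O2 replicates 1 and 3.

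Conceptus product genes rose with VERO cells (median 0.88 over 11, camera adjusted p = 0.0015, adjusted p = 0.496 with an estimated correlation), 9 up and 0 down, also adjusted over the list alone. PAG8 and PAG11, pregnancy-associated glycoproteins, rose by 2.38 and 1.94, HSD3B1 by 2.33 and CYP19A1 by 1.76. Oxidative phosphorylation genes rose (median 0.26 over 44, camera adjusted p = 6.13e-05, adjusted p = 0.496 with an estimated correlation), 12 up and 0 down (13 up adjusted over the list alone). NDUFA1 and NDUFB3 of complex I each rose by 0.59, SDHD of complex II by 0.56 and ATP5F1C of the ATP synthase by 0.55. Unfolded protein and integrated stress response genes rose (median 0.30 over 31, camera adjusted p = 0.00224, adjusted p = 0.496 with an estimated correlation), 13 up and 1 down (14 and 1 adjusted over the list alone), MTHFD2 of mitochondrial one-carbon metabolism by 1.58, the transcription factor DDIT3 by 1.20, CRELD2 by 1.16 and TRIB3 by 1.01. The p53 targets fell (median -0.48 over 23, camera adjusted p = 0.0144, adjusted p = 0.496 with an estimated correlation), 3 up and 13 down (4 and 13 adjusted over the list alone). PLK2 fell by 1.33, SESN1 fell by 1.28, ZMAT3 fell by 1.19, and GADD45G rose by 1.15. Ribosomal protein genes rose (median 0.14 over 47, camera adjusted p = 0.0141, adjusted p = 0.747 with an estimated correlation), 5 up and 0 down (2 up adjusted over the list alone), RPL35 by 1.15, RPL7 by 0.68, RPL37 by 0.36 and RPS16 by 0.32. Ciliated oviduct markers fell (median -0.65 over 14, camera adjusted p = 0.00771, adjusted p = 0.496 with an estimated correlation), 1 up and 6 down (1 and 7 adjusted over the list alone). TPPP3 fell by 1.75, SPMIP6 fell by 1.58, TEKT2 fell by 1.42 and CFAP126 fell by 0.84.

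Blocked by slide, the adjusted p was 0.00251 for conceptus products, 9.10e-05 for oxidative phosphorylation, 0.00343 for the unfolded protein response, 0.0164 for p53 targets, 0.0173 for ribosomal proteins and 0.0110 for ciliated markers. Within slides 1 and 2 the medians were 0.87 and 1.05, 0.31 and 0.21, 0.19 and 0.45, -0.38 and -0.59, 0.16 and 0.09, and -0.31 and -0.82. Ribosomal proteins lost the call without 20% O2 replicate 4 (adjusted p = 0.142) or VERO replicate 1 (0.0694). They also lost it under quantile normalization (0.442, median 0.05), where the median of oxidative phosphorylation was 0.17; that of ciliated markers was -0.26 under normexp. Over 18 alternatives the adjusted p ran from 2.78e-04 to 0.00616 for conceptus products, 3.53e-06 to 0.0123 for oxidative phosphorylation, 1.49e-04 to 0.0152 for the unfolded protein response, 0.00721 to 0.0380 for p53 targets, 5.36e-04 to 0.442 for ribosomal proteins and 0.00233 to 0.0267 for ciliated markers.

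**Figure D2:**
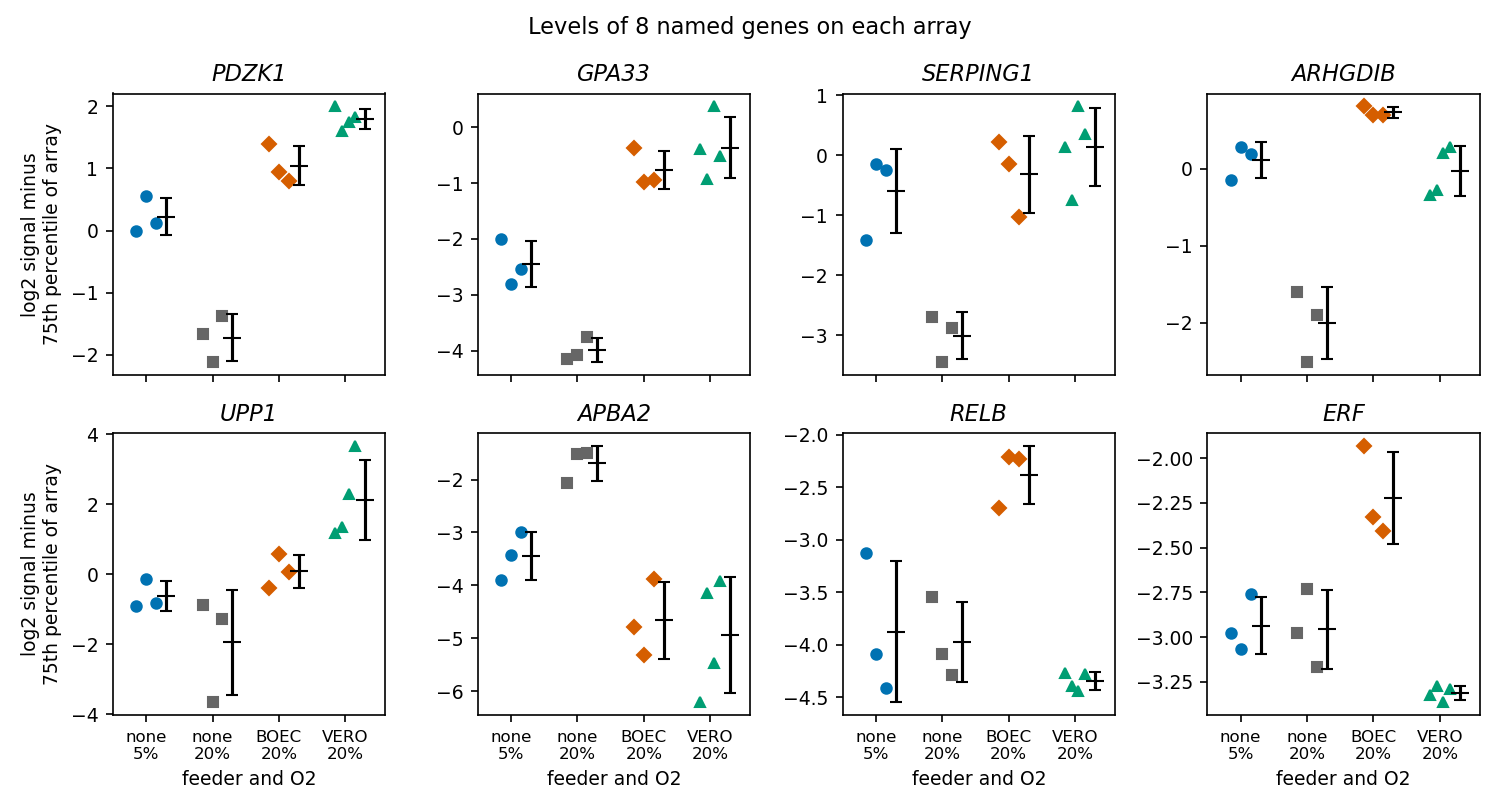
Levels of 8 genes (log2 signal relative to the 75th percentile of the array) per array, with bars for the mean ± SD of each group. PDZK1, GPA33, SERPING1, ARHGDIB and UPP1 were higher with VERO cells than at 20% O2 without feeder and APBA2 was lower, while RELB and ERF were higher with BOEC than with VERO cells.

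The fourth comparison set the feeders against each other. RELB, a subunit of NF-kB, was higher with BOEC, at -2.38 ± 0.27 (SD, n = 3) against -4.35 ± 0.09 (SD, n = 4), a 3.90-fold difference. ERF, a repressor of the ETS family, was 2.13-fold higher with BOEC (-2.22 ± 0.25 against -3.31 ± 0.04), and the keratin KRT80 was 2.06-fold lower (-0.84 ± 0.12 against 0.20 ± 0.24). ARRDC4 was at least 1.05-fold higher with BOEC; it was above background on 1 of 3 BOEC arrays and on 0 of 4 VERO arrays. These and LOC613358, 5.54-fold lower, and the transcript ENSBTAT00000059268, 2.45-fold higher, the last 2 outside the naming rule and chosen after their values were seen, were the 6 features that passed in limma, all at adjusted p = 0.034 (4 up, 2 down).

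An unadjusted p below 0.05 was reached by 2469 features. RELB (ENSBTAT00000065862) lies at 53099825 to 53127762 on chromosome 18 and ERF (ENSBTAT00000000437) at 51350921 to 51357467 on it. With the slide as a block 15 passed (9 up, 6 down), the 4 named genes among them at 0.0476; RELB differed by 1.63 and 2.14 within slides 1 and 2, and each slide alone gave 0 in limma (2593 and 1990 at an unadjusted p below 0.05). Quantile normalization gave 2 up and 3 down, normexp 0 and 1, and the series matrix, with a median over all genes of -0.17, 1 and 7. The count was 1, 13 and 0 without 5% O2 replicates 2, 3 and 4, 0, 0 and 10 without 20% O2 replicates 1, 3 and 4, 31, 1 and 1 without BOEC replicates 2, 3 and 4, and 0 without any 1 VERO array. In limma's fits that called 0, between 1787 and 2776 features had an unadjusted p below 0.05. With the replicate number as a block limma called 0 as well (2078 at an unadjusted p below 0.05). RELB lost its call without VERO replicates 1, 2, 3 or 4 (adjusted p = 0.132, 0.112, 0.0604 and 0.114), 5% O2 replicate 4 (0.0612), 20% O2 replicates 1 or 3 (0.0648 and 0.059) or BOEC replicates 3 or 4 (0.0849 and 0.105). ERF, KRT80 and ARRDC4 lost theirs without the same arrays or 5% O2 replicate 2, except that ARRDC4 kept it without BOEC replicate 3. Normexp ended all 4 calls (0.0645 for RELB, ERF and KRT80, 0.156 for ARRDC4), the series matrix those of ARRDC4 and ERF (0.0895 and 0.0925), the mean of probes those of ARRDC4, ERF and KRT80 (0.121, 0.0839 and 0.0572) and quantile normalization that of RELB (0.0592). Over the 20 alternatives run for named genes the adjusted p of the 4 ran from 0.00254 to 0.156.

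Inflammation and NF-kB targets were higher with BOEC than with VERO cells (median 0.46 over 17, camera adjusted p = 0.0020, adjusted p = 0.526 with an estimated correlation), with RELB alone called (4 higher and 1 lower adjusted over the list alone). Oxidative phosphorylation genes were lower (median -0.22 over 44, camera adjusted p = 4.19e-08, adjusted p = 0.575 with an estimated correlation), with 0 called by limma, also adjusted over the list alone; ATP5F1C differed by -0.45 (adjusted p = 0.139) and ATP5PB by -0.30. The unfolded protein response was lower (median -0.32 over 31, camera adjusted p = 4.07e-06, adjusted p = 0.575 with an estimated correlation), with 0 called and 3 lower adjusted over the list alone, DDIT3 differing by -0.96 (0.128) and HERPUD1 by -0.68. Metal response genes were lower (median -0.45 over 7, camera adjusted p = 0.0457, adjusted p = 0.575 with an estimated correlation), with 0 called and 3 lower adjusted over the list alone, the metallothionein MT2A differing by -1.08 (0.104) and the zinc exporter SLC30A1 by -0.45. Blocked by slide, the adjusted p was 0.00188, 6.96e-08, 6.73e-06 and 0.0742, which ends the call of the metal response, and the medians within slides 1 and 2 were 0.56 and 0.26, -0.27 and -0.18, -0.02 and -0.46, and -0.54 and -0.02. Inflammation lost the call without BOEC replicate 2 (adjusted p = 0.163). The metal response lost it without 5% O2 replicate 2 (0.0559), 20% O2 replicates 1 or 4 (0.0549 and 0.0569), BOEC replicates 2 or 3 (0.321 and 0.0943), or VERO replicates 1 or 2 (0.0565 and 0.0842). It also lost it under quantile normalization (0.0605) and with the replicate number as a block (0.142). Its median was -0.28 without VERO replicate 2 and -0.22 under normexp, and that of the unfolded protein response -0.21 without BOEC replicate 4. Across 18 alternatives the adjusted p ran from 2.41e-04 to 0.163 for inflammation, 1.86e-13 to 9.67e-05 for oxidative phosphorylation, 1.20e-09 to 0.00137 for the unfolded protein response and 0.00583 to 0.321 for the metal response.

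**Figure D3:**
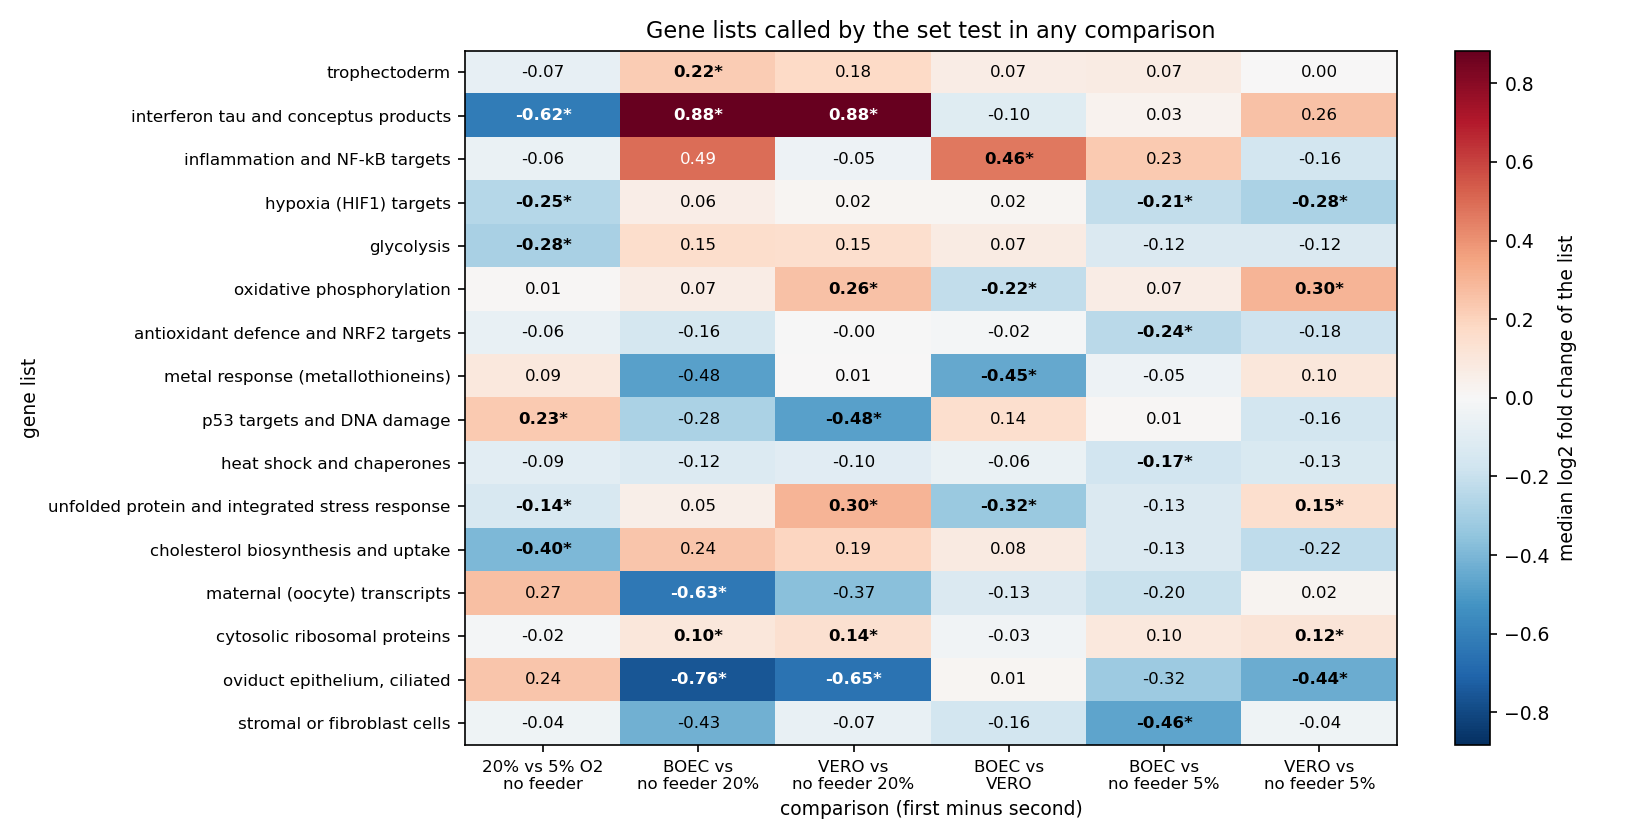
Median log2 fold change (colour scale) of the 16 lists called in at least 1 comparison, with the lists as rows and the 6 comparisons as columns; an asterisk marks a camera adjusted p below 0.05 at the preset correlation. Conceptus products have medians of -0.62 at 20% against 5% O2 and 0.88 with each feeder against none.

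The last comparisons set each feeder at 20% O2 against the 5% O2 control, so that feeder and oxygen differ together. With BOEC, GPA33 was 3.22-fold higher than at 5% O2 (-0.76 ± 0.34 against -2.45 ± 0.41, SD, n = 3 each, adjusted p = 0.0241), SEC16A, of vesicle exit from the endoplasmic reticulum, 3.74-fold higher (0.0318) and NFKB1, of NF-kB, 3.04-fold higher (0.0132, above background on 1 of 3 arrays at 5% O2). ASCL2, a transcription factor of the trophoblast lineage, was 6.39-fold lower (0.0402) and PGAM2, of glycolysis, 6.12-fold lower (0.0318). ADTRP, not well above background at 5% O2, was at least 3.19-fold higher (0.0187). The glutathione transferase GSTA1 and SDR16C5, not well above background with BOEC, were at least 1.88- and 2.64-fold lower (0.0411 and 0.0307).

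In limma 376 of 16300 features passed, 113 up and 263 down (20 and 412 with the series matrix, whose median over all genes lay at -0.10), and 280 with the slide as a block, where ASCL2 did not (adjusted p = 0.0525; -0.92 and -3.56 within slides 1 and 2). Slide 2 alone gave 13 (1 up, 12 down) and slide 1 alone 0 in limma, where 1508 had an unadjusted p below 0.05. The count was 54, 102 and 57 without 5% O2 replicates 2, 3 and 4, 217 and 237 without 20% O2 replicates 1 and 4, 654 and 58 without BOEC replicates 2 and 3, and 231 and 177 without VERO replicates 1 and 4. Each of the 8 named genes lost its call without at least 1 array. GPA33 did so without 5% O2 replicates 3 or 4 or BOEC replicate 3 (adjusted p = 0.0768, 0.0866 and 0.0626), NFKB1 without 5% O2 replicate 4 or BOEC replicate 3 (0.0519 and 0.0516), and ADTRP without 5% O2 replicates 2 or 3 or BOEC replicate 3 (0.0633, 0.06 and 0.0764). The other 5 did so without each 5% O2 array and BOEC replicate 3, with an adjusted p of up to 0.146. Normexp ended the calls of ADTRP and NFKB1 (0.0684 each), GSTA1 (0.802) and SDR16C5 (0.527), quantile normalization that of SDR16C5 (0.0925), the series matrix that of GSTA1 (0.128) and the mean of probes that of GPA33 (0.0842). Over the 20 alternatives run for named genes the adjusted p of the 8 ran from 0.00319 to 0.802.

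HIF1 targets were lower with BOEC than at 5% O2 (median -0.21 over 34, camera adjusted p = 0.00258, adjusted p = 0.68 with an estimated correlation), 0 up and 1 down (6 down adjusted over the list alone), DDIT4, a stress-induced inhibitor of mTOR, having fallen by 1.24. Antioxidant genes were lower (median -0.24 over 44, camera adjusted p = 0.00396, adjusted p = 0.68 with an estimated correlation), 2 up and 5 down (4 and 12 adjusted over the list alone). GSTA2 fell by 2.28, GSTM3 fell by 2.08 and NQO1 fell by 1.38. Heat shock genes were lower (median -0.17 over 19, camera adjusted p = 0.00941, adjusted p = 0.68 with an estimated correlation), 0 up and 2 down, also adjusted over the list alone; the chaperones HSPB8 and SERPINH1 fell by 1.82 and dropped by 1.80. Stromal markers were lower (median -0.46 over 14, camera adjusted p = 0.0326, adjusted p = 0.68 with an estimated correlation), 0 up and 2 down (6 down adjusted over the list alone); S100A4 fell by 1.80 and COL1A1, a collagen, fell by 1.56. The adjusted p with the slide as a block was 0.00323, 0.00323, 0.00734 and 0.0523, which ends the call of stromal markers, and the medians within slides 1 and 2 were -0.12 and -0.31, -0.15 and -0.33, -0.14 and -0.19, and -0.30 and -0.65. HIF1 targets lost the call without 5% O2 replicate 3 (adjusted p = 0.101), and stromal markers without 5% O2 replicate 3 (0.101), 20% O2 replicates 3 or 4 (0.0550 and 0.0541) or BOEC replicate 3 (0.0823). Stromal markers also lost it under normexp (0.0528, median -0.13) and with the replicate number as a block (0.0522). The median of antioxidant genes was -0.11 under normexp, and that of heat shock genes was -0.29 under quantile normalization. The median of HIF1 targets was -0.09 without 5% O2 replicate 3, that of heat shock genes -0.28 without BOEC replicate 2, and that of stromal markers -0.74 and -0.25 without BOEC replicates 2 and 4. Across 18 alternatives the adjusted p ran from 2.80e-05 to 0.101 for HIF1 targets, 1.91e-04 to 0.0455 for antioxidant genes, 3.50e-05 to 0.0455 for heat shock and 0.00728 to 0.101 for stromal markers.

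With VERO cells, UPP1 was 6.68-fold higher than at 5% O2 (2.12 ± 1.13, n = 4, against -0.62 ± 0.41, n = 3, adjusted p = 0.0361) and SLC27A2, a fatty acid transporter, 4.61-fold higher (0.023). RBMS3 and the secreted ligand WNT16, not well above background at 5% O2, were at least 3.07- and 2.35-fold higher (0.0079 and 0.0241). TXNIP, ARRDC4 and the cytochrome P450 gene CYP2C90, not well above background with VERO cells, were at least 3.75-, 2.26- and 2.07-fold lower (adjusted p = 0.00277, 4.56e-04 and 0.0072). ARMCX6 was 9.66-fold lower (0.0216, above background on 1 of 4 VERO arrays).

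In limma 1078 of 16300 features passed, 475 up and 603 down, and 981 with the slide as a block, including all 8 named genes. Slide 2 alone gave 29 (2 up, 27 down) and slide 1 alone 0 in limma, where 2432 had an unadjusted p below 0.05. The count was 413, 291 and 497 without 5% O2 replicates 2, 3 and 4 and 480 and 413 without VERO replicates 1 and 4. RBMS3, TXNIP, ARRDC4 and CYP2C90 kept their calls without any array, but normexp ended them (adjusted p = 0.220, 0.0762, 0.125 and 0.274) and that of WNT16 (0.281). Over the 20 alternatives run for named genes the adjusted p of the 8 ran from 5.30e-05 to 0.281. UPP1 lost its call without 5% O2 replicates 2, 3 or 4 (adjusted p = 0.11, 0.0873 and 0.102) or VERO replicates 3 or 4 (0.0624 and 0.0789), and WNT16 without the same 3 arrays at 5% O2 (0.0825, 0.0518 and 0.0825) or VERO replicate 4 (0.0683). SLC27A2 and ARMCX6 lost it without any 1 array at 5% O2 or without VERO replicate 1, with an adjusted p of up to 0.0808 and 0.0835.

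Oxidative phosphorylation genes were higher with VERO cells than at 5% O2 (median 0.30 over 44, camera adjusted p = 6.94e-10, adjusted p = 0.664 with an estimated correlation), 7 up and 0 down (18 up adjusted over the list alone). SDHD rose by 0.68, NDUFB3 by 0.58, NDUFV1 by 0.56 and UQCRQ by 0.44. HIF1 targets were lower (median -0.28 over 34, camera adjusted p = 0.00198, adjusted p = 0.664 with an estimated correlation), 1 up and 5 down (2 and 16 adjusted over the list alone); ANKRD37 fell by 2.53, DDIT4 fell by 1.26, MXI1 fell by 1.15 and ADM fell by 0.90. The unfolded protein response was higher (median 0.15 over 31, camera adjusted p = 0.0355, adjusted p = 0.664 with an estimated correlation), 3 up and 0 down, also adjusted over the list alone: DDIT3 by 1.19, PPP1R15A by 0.74 and SDF2L1 by 0.59. Ribosomal protein genes were higher (median 0.12 over 47, camera adjusted p = 0.0145, adjusted p = 0.715 with an estimated correlation), with RPL35, up by 0.72, alone called in both adjustments (1 adjusted over the list alone). Ciliated oviduct markers were lower (median -0.44 over 14, camera adjusted p = 0.0176, adjusted p = 0.664 with an estimated correlation), 0 up and 5 down, also adjusted over the list alone; TEKT2 fell by 1.33, SPMIP6 fell by 1.24, TPPP3 fell by 1.0 and CFAP126 fell by 0.65.

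With the slide as a block the adjusted p was 1.89e-09 for oxidative phosphorylation, 0.00278 for HIF1 targets, 0.0393 for the unfolded protein response, 0.0290 for ribosomal proteins and 0.0262 for ciliated markers, and the medians within slides 1 and 2 were 0.29 and 0.27, -0.20 and -0.27, 0.13 and 0.27, 0.13 and 0.06, and -0.10 and -0.56. HIF1 targets lost the call without 5% O2 replicate 3 (adjusted p = 0.0585), and the unfolded protein response without 5% O2 replicate 4 (0.0587) or VERO replicates 2, 3 or 4 (0.0650, 0.0822 and 0.0791). Ribosomal proteins lost it without 5% O2 replicate 4 (0.0587) or VERO replicates 1 or 2 (0.0767 and 0.0623), and ciliated markers without 5% O2 replicate 4 (0.0568) or VERO replicate 3 (0.0641). The median of the unfolded protein response was 0.23 without VERO replicate 1 and that of ciliated markers -0.23 without 5% O2 replicate 4. Quantile normalization ended the calls of the unfolded protein response (0.0883) and ribosomal proteins (0.958, median 0.01) and normexp that of ciliated markers (0.0512, median -0.12). The replicate number as a block ended that of ribosomal proteins as well (0.0562). Across 18 alternatives the adjusted p ran from 4.48e-12 to 7.01e-06 for oxidative phosphorylation, 7.20e-05 to 0.0585 for HIF1 targets, 0.00111 to 0.0883 for the unfolded protein response, 1.01e-04 to 0.958 for ribosomal proteins and 0.00269 to 0.0641 for ciliated markers.

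The fold changes of the feeders were then set beside each other and beside that of lower oxygen, all against the 20% O2 arrays without feeder. Across 16300 features, which are not independent replicates, r was 0.815 for BOEC and VERO, with 80.4% of features of the same sign. Unchanged groups sharing those 3 control arrays, with each feature drawn independently, gave a mean r of 0.534 and at most 0.574 in 1000 draws. The covariance was 0.30, against a simulated 0.0349, a difference of 0.265. For BOEC and 5% O2, r was 0.650 (simulated mean 0.50, highest 0.535) and the covariance 0.160, 0.125 above the simulated one. For VERO and 5% O2, r was 0.672 (simulated mean 0.534, highest 0.567) and the covariance 0.183, 0.148 above it. Within slides 1 and 2 the 3 correlations were 0.615 and 0.793, 0.671 and 0.613, and 0.597 and 0.673, and with the slide as a block 0.817, 0.650 and 0.672. Slide 1 holds 1 array without feeder at 20% O2, and no unchanged groups were simulated within slides, so the values within slides cannot be set against the simulated ones.

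Of the features that rose with BOEC, 891 also rose with VERO cells, against 163 for independent lists, and of those that fell, 1057 also fell, against 173. None rose with one feeder and fell with the other by limma's calls. Unchanged groups with the same controls shared 0 rises and at most 1 fall in 100 draws, but as they call almost nothing this gives no expected overlap for lists of this length. With 3 control arrays no split leaves at least 2 in each part, so part of the excess may come from the shared controls.

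Markers of other cell types were measured in the same arrays. Secretory oviduct markers gave 2 up and 2 down with BOEC and 4 up and 3 down with VERO cells, against none. TFF3 was at least 3.32- and 3.85-fold lower, MUC1 rose by 2.41 and 2.62, ANXA4 by 0.99 and 1.32, LTF fell by 0.93 with BOEC and OVGP1, an oviduct glycoprotein, rose by 1.20 with VERO cells. Kidney markers gave 1 and 2 up (LRP2 by 0.68 and 0.90, CAV1 by 2.31 with VERO cells). Stromal markers gave 1 up and 5 down and 2 up and 5 down; COL1A1 fell by 2.08 and by 2.41 and ACTA2 rose by 1.53 with VERO cells. Cumulus markers gave 4 and 6 up, HSD3B1, CYP19A1 and PTGS2, which the conceptus list also holds, among them, and CYP11A1 by 2.23 and 1.93. Leukocyte markers gave 1 and 2 down (CORO1A fell by 1.32 and dropped by 1.29), red blood cell markers 1 up (ALAS2, by 3.12) and 1 up and 1 down, and sperm markers 1 up and 2 down and 1 up and 3 down (TNP1 up by 2.04 and 2.93). Other lists hold 2 of the 21 secretory, 0 of the 22 ciliated, 5 of the 20 kidney, 1 of the 18 stromal, 0 of the 16 leukocyte, 4 of the 17 cumulus, 0 of the 10 red blood cell and 1 of the 13 sperm markers.

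The cell lists other than ciliated and stromal markers, 6 in all, and 9 gene lists were called in no comparison. Inner cell mass and pluripotency genes had medians of -0.31 to 0.19 and a smallest camera adjusted p of 0.102, primitive endoderm genes -0.20 to 0.01 (0.302), interferon-stimulated genes -0.13 to 0.31 (0.0647) and cell cycle genes -0.17 to 0.15 (0.0908). Growth factor signalling ran from -0.19 to 0.19 (0.102), fatty acid and lipid droplet genes from -0.06 to 0.12 (0.449), tight junction and fluid transport genes from -0.06 to 0.17 (0.410), apoptosis genes from -0.06 to 0.14 (0.441) and DNA methylation and imprinted genes from -0.07 to 0.09 (0.556). Among the cell lists, secretory oviduct markers ran from -0.61 to 0.36 (0.102), kidney markers from -0.19 to 0.36 (0.102), leukocyte markers from -0.49 to 0.31 (0.0537), cumulus markers from -0.08 to 0.63 (0.0915), red blood cell markers from -0.20 to 0.02 (0.573) and sperm markers from -0.50 to 0.15 (0.0604).

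Besides genes, the array carries classes of repeat and small RNA features, which were examined after their values were seen. Features named for endogenous retrovirus clones, remnants of retroviral genomes, had a median log2 fold change of 0.68 at 20% against 5% O2 (213 features, 15 up and 0 down, camera p = 1.90e-43 and p = 0.0277 with an estimated correlation). With BOEC against none their median was -0.76 (1 up, 118 down, p = 2.66e-31 and p = 0.0549 with an estimated correlation), and with VERO cells -0.77 (0 up, 132 down, p = 4.90e-29 and p = 0.0631 with an estimated correlation). Blocked by slide, the camera p was 9.49e-45, 3.10e-32 and 1.78e-30. Small nucleolar RNA features of the SNORD112 and SNORD113 families lie together at 67466611 to 67543644 on chromosome 21. All 28 rose with BOEC (median 2.42) and 24 with VERO cells (median 1.95), and 1 fell at 20% against 5% O2 (median -1.79); the p with an estimated correlation was 0.0583, 0.152 and 0.0569. Blocked by slide, the camera p of the feeder comparisons was 7.93e-19 and 5.42e-11. Without 20% O2 replicates 1 and 3 the rises numbered 18 and 17 with BOEC and 13 and 11 with VERO cells. Against 5% O2, 0 of the 28 were called with either feeder. The medians there were 0.64 with BOEC (camera p = 1.46e-04, p = 0.388 with an estimated correlation) and -0.05 with VERO cells (0.671 and 0.922).

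**Figure D4:**
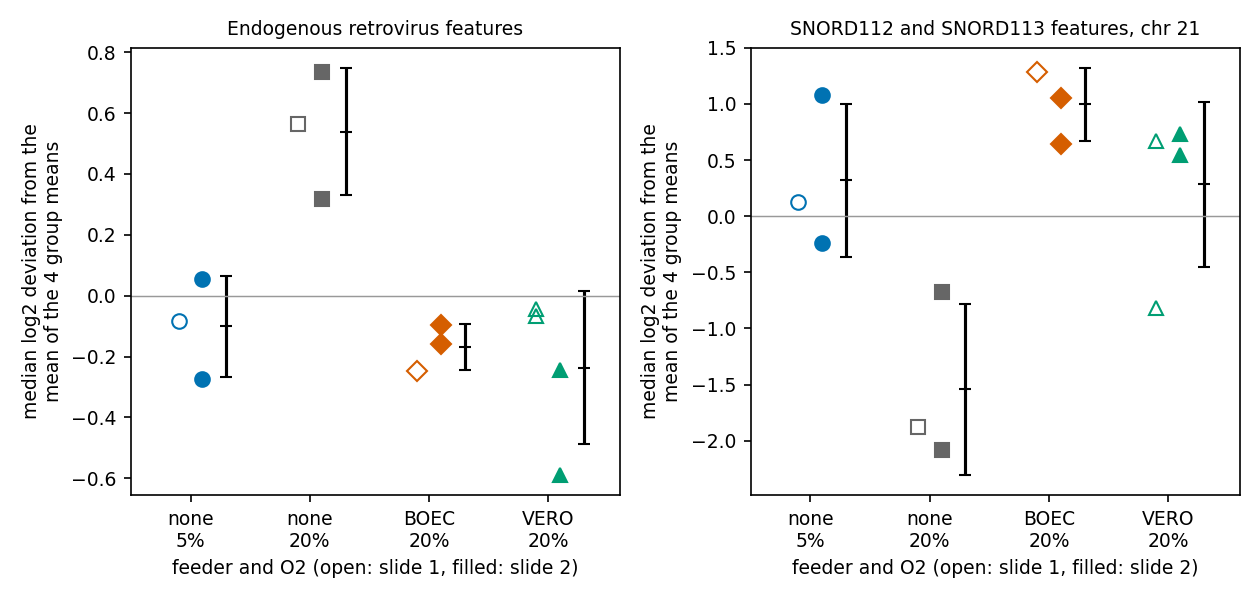
Median deviation (log2) of the retrovirus features (left) and of the 28 SNORD112 and SNORD113 features (right) from the mean of the 4 group means, per array; open points are slide 1, filled points slide 2, and bars the mean ± SD of each group. The 3 arrays at 20% O2 without feeder, at 0.32 to 0.73, lay above all others on the left; on the right they lay at -2.08 to -0.67, and VERO replicate 2 at -0.82.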

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

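The features of the BOEC and VERO contrast outside the naming rule and the locus on chromosome 21 were examined after their values were seen. Over 68 quantities tested within the 4 VERO arrays, most of them levels of named genes, 2 put 1 array far from the other 3. Chance does so in about 1 test in 20, so these 2 are no more than chance would give. VERO replicate 2 had a median deviation of -0.82 for the SNORD112 and SNORD113 features, against 0.55 to 0.74 in the other VERO arrays (a gap of 0.878 of the range). It also had the lowest level of NFKB1, -5.59 against -5.26 to -5.23 (a gap of 0.922 of the range).

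The effects of the feeders, each against the same arrays without feeder, differed by limma's test of BOEC against VERO for 6 features, all at adjusted p = 0.034. The log2 fold changes were 1.96 for RELB, 1.09 for ERF, 1.29 for ENSBTAT00000059268, -1.04 for KRT80 and -2.47 for LOC613358. For ARRDC4 the fitted difference was 2.32 and the bound at least 1.05-fold. The probes labelled luciferase, which name no bovine gene, were above background on all arrays, with a mean log2 signal of 15.98 or more on each of the 13 arrays. Relative to the 75th percentile they stood at 7.56 ± 0.08 at 5% O2, 8.09 ± 0.28 at 20% O2 without feeder, 7.98 ± 0.42 with BOEC (SD, n = 3 each) and 7.97 ± 0.29 with VERO cells (SD, n = 4).

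Other divisions of the same arrays were counted. For VERO against none, 1 of 35 splits, the real one, called as many features (the highest of the others called 633). For BOEC against VERO it was 1 of 35 (highest other 5) and for VERO against 5% O2 1 of 35 (highest other 76). For the F test it was 1 of 100 drawn (highest other 112). The share thus lay below the bound of 0.05 for the counts of 4444, 1078 and 3410. Of 35 splits 1 is the fewest possible, and the shares were not adjusted over the comparisons. Chance is therefore made less likely for these counts but is not excluded. The 6 of BOEC against VERO exceed the highest other by 1 feature and fall to 0 without any 1 VERO array, so little rests on them. For 20% against 5% O2, BOEC against none and BOEC against 5% O2 the 10 splits are too few for a share below 0.05; the real counts were 70, 2473 and 376, and the highest other 0.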

How the results depend on the processing

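The fits on each slide alone, the slide block for lists and named genes, and features with a symbol alone were chosen after seeing the data. Counts of features that moved by over 1.5 times are given here, and the cause was not tested except where fewer arrays or features entered. For 20% against 5% O2 (70) the count was 174 with quantile normalization, 118 with normexp, 2 without a filter, 197 with probes above background on all 13 arrays, 37 with the series matrix, 369 with trended and robust variances, 814 with array weights, 31 with the slide block, 203 with every probe, 34 at 2-fold or more, 2 with the 2 groups alone, 36 with symbols alone and 0 in slide 1 and in slide 2. For BOEC against none (2473) it was 1355 with normexp, 1284 without a filter, 1434 with the series matrix, 848 at 2-fold or more, 907 with the 2 groups alone, and 0 and 550 within the slides. For VERO against none (4444) it was 1256 at 2-fold or more, and 0 and 1245 within the slides. For BOEC against VERO (6) it was 1 with normexp, 0 without a filter, 13 on all 13 arrays, 1 with the mean of probes, 39 with trended variances, 14 with array weights, 15 with the slide block, 1 with every probe, 2 with the 2 groups alone, and 0 and 0 within the slides. For BOEC against 5% O2 (376) it was 203 with normexp, 99 without a filter, 199 at 2-fold or more, 73 with the 2 groups alone, and 0 and 13 within the slides. For VERO against 5% O2 (1078) it was 420 without a filter, 593 with the series matrix, 2331 with array weights, 387 at 2-fold or more, and 0 and 29 within the slides. The F test (3410) gave 1771 without a filter, 5540 with array weights, 1375 at 2-fold or more, and 0 and 201 within the slides. In limma's fits that called 0, an unadjusted p below 0.05 was reached by 2571 features (BOEC against VERO without a filter), by 1837, 2735, 3988, 2593, 1508, 2432 and 3074 in slide 1, in the order above, and by 2059 and 1990 in slide 2 for the first and the fourth comparison; slide 1 alone leaves 1 residual degree of freedom. With the replicate number as a block the counts were 0, 1318, 0, 125, 342 and 1818 for 20% against 5% O2, BOEC against none, BOEC against VERO, BOEC and VERO against 5% O2 and the F test (2620 and 2078 at an unadjusted p below 0.05 where limma called 0). Deviations of same-numbered arrays correlated at -0.263 to 0.279 over 16 pairs, 3 above 0.1, and 1 of 13 arrays correlated best with its own number. Leaving out each array gave 0 to 129, 1054 to 2656, 2416 to 4999, 0 to 31, 54 to 654, 291 to 1190 and 1793 to 4494 features in the same order, correlations of 0.738 to 0.841, 0.60 to 0.70 and 0.637 to 0.729, and 3 to 9, 3 to 7, 5 to 8, 3 to 6, 2 to 7 and 3 to 9 lists. With an estimated correlation 0 lists were called in all 6 comparisons; quantile normalization called 3 for BOEC against none and normexp 10 for VERO against 5% O2. Of 80 calls of named genes, 77 were kept with quantile normalization, 80 with median centring, 51 with normexp and 47 with the replicate block. The slide block kept 67, the series matrix 63 and the mean of probes 70. Over the 13 fits without 1 array, with each call counted in each fit, 797 were kept and 243 lost. Of 30 calls of lists, quantile normalization kept 23, median centring 30, normexp 23, the replicate block 25 and the slide block 28. Counted in the same way without 1 array, 352 were kept and 38 lost. Lists that were not called became so 6, 15, 4 and 1 times with quantile normalization, normexp, the replicate block and the slide block. No called list or named gene changed sign, except that ribosomal proteins had a median of -0.01 with BOEC against none within slide 1. Normexp moved the median of all genes to 0.11 for BOEC against 5% O2. Scan date coincides with the slide and was not run separately. Probes dim against background limit what could be measured, with 56.4% to 65.9% well above it per array.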

Other observations

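The small RNA classes, the gene families and the tests of an earlier developmental state, of all small RNA, of 1 deviating array and of feeders lowering oxygen were chosen after the result was seen. Of 619 features named for the spliceosomal U6 RNA, 156 rose and 1 fell with BOEC against none at 20% O2 (median 0.57) and 268 rose and 0 fell with VERO cells (median 0.53); the class as such was not tested. Of 20 U4 features, 12 and 14 rose (medians 0.70 and 0.65). Among U6atac and U1 features 26 of 29 and 43 of 60 were called up with VERO cells (medians 0.93 and 0.60), against 0 and 1 with BOEC (0.51 and 0.47). BOEC against VERO called 0 features of either class (medians -0.42 and -0.13). The unequal numbers of calls thus show no difference between the feeders, and the classes as such were not tested. The medians of these 4 classes against none stayed above 0 with both feeders under quantile normalization, median centring, normexp and the series matrix. That of U6atac with VERO cells was 0.53 under normexp. Against 5% O2, U6 features gave 0 up and 0 down with BOEC (median 0.25) and 2 up and 1 down with VERO cells (0.22). Calls up against 5% O2 with BOEC and VERO cells were 1 and 1 for U4, 0 and 2 for U6atac and 0 and 25 for U1. Whether probes tell apart features named for the same RNA was not tested, so these calls do not count separate RNAs.

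Pregnancy-associated glycoproteins, secreted by the trophoblast, gave 10 rises among 12 tested members with VERO cells against none (median 1.86). PAG15 rose by 2.58 (adjusted p = 0.00771) and PAG5 by 2.27 (0.00586), while PAG17 (0.0501) and PAG10 (0.689) did not pass. With BOEC 0 passed in limma (median 0.90, 11 of 12 above 0), and at 20% against 5% O2 0 passed (median -1.35), or 1 with quantile normalization. The medians of these 3 comparisons kept their direction under each scaling but shrank under normexp, to 0.89, 0.54 and -0.72. The number called with VERO cells was 9 to 11 under quantile normalization, median centring, normexp, the series matrix and the slide block. Set directly against VERO cells, BOEC gave 0 calls among the 12 glycoproteins (median -0.99), so no member was shown to differ between the feeders. Among the alpha glutathione transferases, 3 of 4 fell with BOEC against 5% O2 (median of fitted values -2.24) and 3 of 4 with VERO cells (median -1.58). GSTA1 was not well above background with BOEC, so the BOEC median rests in part on signal near background. GSTA3 fell by 2.19 (adjusted p = 0.0473) and by 2.43 (0.0144), and all 4 lay below 0 under each scaling in both comparisons. The medians were -0.37 and -0.78 with normexp and the series matrix for BOEC, and -0.54 and -0.74 for VERO cells. The number that passed was 1 with normexp and 2 with the series matrix for BOEC, and 2 with quantile normalization, normexp and the series matrix for VERO cells. The family was already lower at 20% than at 5% O2 without feeder (median -1.29, 0 of 4 above 0). None of the 4 passed there, against 1 with quantile normalization and 2 with normexp. Against none at 20% O2 the medians were -0.67 with BOEC and -0.20 with VERO cells, with 1 down each. The falls against 5% O2 thus cannot be put down to the feeders alone.

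The retrovirus features were lower with both feeders than without at 20% O2. Genomic DNA was taken to give signal on both strands. Over 198 clones with an excess at 20% O2 on the brighter strand, the dimmer strand held 0.0226 of that excess (95% bootstrap interval 0.0124 to 0.0341). The interval measures the spread between clones and not between arrays. The dimmer strand's whole level at 20% O2 was 0.0449 of the brighter strand's (median over clones). The small share of the excess argues against genomic DNA only as far as both strands are labelled alike and read alike by their probes. Neither was checked. Scaling is argued against too, since the median shift closest to 0 over 4 other scalings was -0.57. An earlier developmental state at 20% O2 stays open: maternal transcripts had a median of -0.37 with VERO cells (camera adjusted p = 0.0989) and of -0.63 with BOEC (0.0214). Against 5% O2 the retrovirus medians were -0.09 with BOEC (0 up, 0 down) and -0.07 with VERO cells (0 up, 2 down). The 3 arrays at 20% O2 without feeder thus stood apart from the other 3 groups. A difference made by the feeders at 20% O2 may also stand behind the pattern, and cannot be told from a deviation of those 3 arrays.

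The SNORD112 and SNORD113 features were higher with both feeders than without at 20% O2. A shift of all small RNA by as much is argued against, as the other small RNA features pooled had medians of at most 0.395 and other small nucleolar RNA features of 0.09 and -0.12. Single classes moved more, U4 by 0.70 and 0.65 and U6atac by 0.93 with VERO cells, so a smaller shift of some classes remains. That 1 deviating array made the pattern is argued against too, since without any 1 array at 20% O2 the median stayed at 1.63 or more. A first test counted the calls among the 28 features without replicates 1, 3 and 4. It gave 18, 17 and 26 with BOEC (28 on all arrays) and 13, 11 and 24 with VERO cells (24 on all arrays), and met neither of its bounds. Cross-hybridisation of near-identical copies to 1 RNA stays open: 4 tested microRNA precursors near the locus had medians of 0.42 and 0.21 (0.212 as tested), with 1 and 0 called up. These medians meet the bound set for it in advance, but 4 features are few, below a minimum of 5 that was coded with the test and not stated in the prediction. SNORA79, another small nucleolar RNA within the locus, rose by 1.83 (adjusted p = 0.0173) and 1.36 (0.0263), which goes against it for that 1 feature. A first version of the test had counted SNORA79 as a neighbour against the wording of its prediction, with medians of 0.43 and 0.22 that also met the bound, and was corrected after its result was seen. A change of the whole locus with the feeders may stand beside it, and was not tested otherwise. Against 5% O2, 0 of the 28 features were called with either feeder (medians 0.64 with BOEC and -0.05 with VERO cells). Calls thus came only in comparisons with the 20% O2 arrays without feeder.

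Fold changes of both feeders against none at 20% O2 ran with those of 5% against 20% O2. The lower covariance exceeded the highest simulated one by 0.121, which met the bound set in advance against shared control arrays alone. The draws varied each feature independently, so their range may be too narrow for features that vary together. Shared control arrays therefore stay open as a part of the pattern. Feeder cells may lower the oxygen around the embryos, which stays open: HIF1 targets had medians of 0.0610 and 0.02 with the feeders, with upper bootstrap bounds of 0.153 and 0.196 that reach past the 0.127 such an effect was taken to need. The second part of the bound against it was met: the list was lower with both feeders than at 5% O2 (medians -0.21 and -0.28, camera adjusted p = 0.00258 and 0.00198, adjusted p = 0.68 and 0.664 with an estimated correlation). Without 5% O2 replicate 3 both of these calls were lost (camera adjusted p = 0.101 and 0.0585, medians -0.09 and -0.22). With all arrays the values go against oxygen as low as in the 5% O2 arrays, where the list's median differed by 0.25 in size. That rests on 1 array at 5% O2, and a smaller fall stays open.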
